A study of Homo sapiens with 7 samples.

How the data were processed

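Sorted cells with CD31 and without CD45 from 1 human liver were profiled with the 10X Chromium 3′ kit, and polyadenylated RNA of 6 HUVEC libraries was sequenced, per the labels' protocols. The deposited liver table lists whole-number UMI counts per barcode and gene symbol, only where above 0, and the submitters' processing notes name the build hg19; the aligner and counter are not given in the sources used here. The deposited HUVEC table holds raw read counts per Ensembl gene, not normalised. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36, TopHat2 2.1.0, Bowtie2 2.2.6 and HTSeq 0.11.1 were used with GRCh38, and their settings are not given in the sources used here. The libraries were made with an unstranded or a stranded TruSeq kit, per the labels' protocols, without saying which sample had which, so the strand setting of the counts is unknown. Reads of overlapping antisense genes could therefore be split or shared. Apart from the strand, similar sequence could split or share reads of close paralogues such as CLEC4M and CD209. The same holds for genes with many processed copies, such as RPSA, KRT8 and KRT18, and IGLL5 shares sequence with immunoglobulin lambda genes.

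Gene positions and types came from GENCODE 29 on GRCh38: 58039 of 58302 HUVEC genes were found there and 42343 had a symbol. In the liver data 904 symbols were replaced by current ones from a RefSeq synonym table, for matching only by name, and 15259 of 15908 were found. No liver coordinates are given, as the build differs. The liver table held 190345 barcodes of 18 bases and 3934738 UMIs, and no symbols that begin with MT-, so the planned limit of 20% mitochondrial UMIs had no effect.

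Groups, tests, gene lists, marker lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. HUVEC genes were filtered with edgeR's filterByExpr, scaled by TMM and tested two-sided with edgeR 4.0.16 (glmQLFit with robust, glmQLFTest; R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05. The CPM used the scaled library sizes. The 30 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2, MAF left out), adjusted over the 30 lists, and again with an estimated correlation and with fry. Named were MAF, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 2 and groups that did not overlap, every tested LSEC list gene, and up to 3 genes with the smallest adjusted p in each other list. In the liver the rule named all marker genes and the 10 largest ratios each way among genes with a UMI in at least 10% of cells of the higher class. A few genes outside the rule are named in the closing parts and were chosen after their values were seen. On counts simulated from these libraries, with 15535 genes, the test recovered 23.9% of genes changed by 1.5-fold, 61.2% by 2-fold and 86.4% by 4-fold, with 11 false among 125 calls.

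Liver barcodes with at least 200 genes (844) were kept, Scrublet doublets (7) were removed, and 837 cells were normalised to 10000 UMIs, reduced to 2000 variable genes and 30 principal components and clustered with Leiden at resolution 1.0 (scanpy 1.11.5, Python 3.11.15), giving 8 clusters. On simulated liver cells, 4-fold changes were recovered with a median ratio of 3.35. Levels were UMIs per 1000000 (CPM) summed over the cells of a class, with exact Poisson intervals, and shares have exact Clopper-Pearson intervals at 95%. The 100 genes each way between the sinusoidal class and the vascular and venous classes (pseudocount 10 CPM) formed the liver-derived lists, tested by camera and adjusted over both. A count of 0 was set to a floor of 3 counts over the group.

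The rule that names liver clusters was not fixed beforehand; only the 18 marker lists were. It was settled after results had been seen, in 3 passes. An earlier rule asked for at least 3 markers raised 2-fold and at least 1 marker among the 10 top genes. The rule used here asks for at least 3 markers and 50% of the list, with no other class holding more top genes, and for a top marker only where the median UMI count is under 1 in 3 of the sample's. Under the earlier rule the plasma cell name was also lost in 3 of 4 other clusterings and cell filters. Names changed less between clusterings under the present rule, which was part of the reason for choosing it, so that stability is no independent evidence. Replacing old symbols, joining the portal and central venous lists, and counting genes at least 2-fold apart were also decided after the data had been seen.

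Alternatives were other scalings, no filter or a stricter one (10 counts in every library of a group), a block on the replicate number, each library left out, DESeq2 1.42.0, other thresholds, other list sizes, and other clusterings, cell filters and doublet handling. Chosen after seeing the data were leaving out replicate 3 of both groups, replicate 3 as a batch term, venous cells alone as the vascular class, and the earlier naming rule with and without current symbols. The replicate 3 titles carry a suffix that the labels do not explain. Depth limits low genes, and intervals and floors cover counting error only.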

Results

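The data came from 1 human liver sample and from 6 libraries of HUVEC, endothelial cells of the human umbilical vein that are grown in culture. From the liver, cells with the endothelial surface protein CD31 and without the leukocyte protein CD45 had been sorted and profiled by droplet single-cell RNA sequencing, and 837 cells with 2359675 unique transcript molecules (UMIs) were used. The HUVEC libraries were 3 controls and 3 that carry the label MAF KO, a knockout of the gene of the transcription factor MAF. The titles of all 6 carry the term dox, which the labels do not explain. Total gene counts were 33449391, 42344449 and 40235991 in the controls and 53777001, 37682970 and 46635363 in the libraries labelled MAF KO. Nothing in the labels says whether replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

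In the liver, 192 of 837 cells (22.9%, exact binomial interval 20.1 to 25.9) formed a class like the endothelium of the sinusoids (LSEC-like), the capillaries that line the hepatocyte plates. These cells were rich in FCN3 (15442 UMIs per 1000000, CPM), a lectin of the complement pathway, in CRHBP (5037), in the C-type lectin CLEC4G (4770), and in the scavenger receptors STAB1 (3299) and STAB2 (1874). A second class of 140 cells (16.7%, 14.3 to 19.4) was like vascular endothelium and carried AQP1 (1448), a water channel, and CD34 (364), while STAB2 stood at 193. A further class of 45 cells (5.38%, 3.95 to 7.13) was like venous endothelium, with the adhesion molecules SELE (3941) and SELP (990) and with VWF (1755), the von Willebrand factor. Plasma-cell-like cells made up 213 cells (25.4%, 22.5 to 28.5), with JCHAIN (90018), the joining chain of secreted antibodies, and MZB1 (5057). PTPRC, which encodes CD45, had 0 UMIs in all classes.

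The remaining 247 cells (29.5%, 26.4 to 32.7) stayed unnamed, with a median of 867 UMIs per cell against 1671 in the LSEC-like, 3460 in the vascular and 4055 in the plasma-cell-like class. Among them were 4 cells with 10 of 13 hepatocyte markers, too few to be named as a class. A further 97 unnamed cells formed a cluster with 6 of 15 LSEC markers raised, namely STAB1, STAB2, CLEC4G, CLEC4M, FCN3 and OIT3. The naming rule asks for a larger share of the list, so these 97 cells are outside the LSEC-like share of 22.9%. The other 146 unnamed cells formed a cluster with 1 of 13 hepatocyte markers raised, ALB. The vascular class also carried 11 of 15 markers of periportal sinusoidal cells beside all 10 of its own list, and the venous class carried 10 of 11 portal and 7 of 8 central venous markers, so portal and central veins were not separated. With 1 sample there was no test, and all intervals of the liver cover counting error only. At a coarser clustering (resolution 0.5) the LSEC-like class took 52.0% of cells and no vascular or venous class was named. A separate cluster of 182 cells had no name there, and which cells moved between classes was not traced.

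MAF was highest in the LSEC-like class, at 1085 CPM (exact Poisson interval 985 to 1192). It stood at 266 (224 to 314) in the vascular, at 212 (146 to 298) in the venous and at 21.1 (13.1 to 32.3) in the plasma-cell-like class. A MAF UMI was found in 55.7% of LSEC-like cells (48.4 to 62.9), 35.7% of vascular cells (27.8 to 44.2), 24.4% of venous cells (12.9 to 39.5) and 7.98% of plasma-cell-like cells (4.72 to 12.5). After each cell was thinned to 1000 UMIs, which left out 53, 9, 6 and 26 cells of these classes, the shares were 47.5%, 19.8%, 17.9% and 2.67%. Barcodes with fewer than 50 genes had MAF at 526 CPM, above the level in the vascular and venous classes. These barcodes were taken to hold mainly free RNA, which was not tested. They held IGLL5 at 27104 CPM and JCHAIN at 12724, against 454 and 349 in the vascular class. The vascular class thus held little RNA of that make-up, which argues against such RNA as the main source of its MAF. These values do not settle the venous class.

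**Figure D1:**
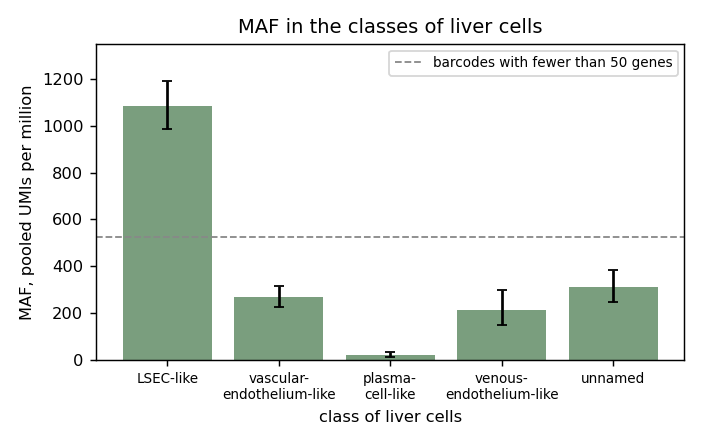
Pooled MAF level (CPM, vertical axis) in each class of liver cells (bars), with exact Poisson intervals. The LSEC-like class, at 1085, stands above the level of 526 in barcodes with fewer than 50 genes (dashed line), and the other classes lie below it.

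Between the LSEC-like class and the vascular and venous classes combined, 320 genes were at least 2-fold higher in the sinusoidal cells and 382 in the others, by ratios of pooled levels. With at least 500 genes per cell these counts were 468 and 389, so which side had more genes depended on the filter. The amino acid transporter SLC7A8 was 87.4-fold higher in sinusoidal cells (interval 29.4 to 429), resting on 3 UMIs in the others. The ratio was 23.1 (15.9 to 34.7) for RELN, a secreted matrix protein, 18.6 (14.1 to 24.9) for MS4A6A, 15.6 (13.0 to 18.8) for CLEC4M and 13.7 (12.0 to 15.8) for CLEC4G. PVALB, FRZB, CLEC1B and SH3TC1 were also among the 10 largest ratios on that side. On the other side, FBLN2, a matrix protein, was at least 69.8-fold higher and SELP at least 30.9-fold higher, each with 0 UMIs in sinusoidal cells and set against a floor of 3 counts. The ratio was 55.3 (26.7 to 138) for the cytokine IL6, 53.5 (22.8 to 166) for VWF and 28.3 (17.6 to 48.9) for AQP1, and CPE, VIM, SYNPO, CD34 and CCN2 completed that group. CLEC4M, CLEC4G and CLEC1B on the sinusoidal side and VWF, CD34, AQP1, SELP and CPE on the other are also markers that helped to name these classes.

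In HUVEC, MAF RNA went against the label. MAF, on the minus strand of chromosome 16 from 79585843 to 79600714 (GRCh38), had 16, 18 and 3 reads in the controls and 59166, 43227 and 64217 reads in the libraries labelled MAF KO. The level was 0.317 ± 0.214 CPM (SD, n = 3) in controls and 1244 ± 167 (SD, n = 3) in the libraries labelled MAF KO. The log2 fold change was 11.95 (SE 0.48, edgeR adjusted p = 1.19e-04). The titles of all HUVEC libraries carry the term dox. The term MAF stands only in the titles of the 3 libraries labelled MAF KO, and those of the 3 controls carry Ctl in its place. The labels do not explain these terms, while description and genotype give a knockout. Every direction below is that of the libraries labelled MAF KO over the controls, with MAF RNA higher in the former.

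**Figure D2:**
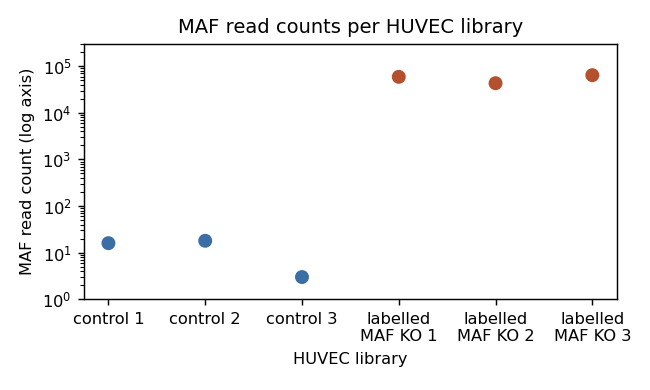
MAF read counts (vertical log axis) in each HUVEC library (points). The 3 controls hold 16, 18 and 3 reads, and the 3 libraries labelled MAF KO hold 59166, 43227 and 64217.

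Beside MAF, the largest rises were those of TIMP4, an inhibitor of metalloproteinases, CEMIP, which takes part in hyaluronan breakdown (log2 fold change 11.57, SE 0.63), the mannose receptor MRC1 (11.41, SE 0.58), CRHBP (10.77, SE 0.42), CD200R1, STAB2 (9.50, SE 0.83), SLC7A8 (8.80, SE 0.52), HABP2 (8.62, SE 0.63), GCNT4 (8.18, SE 0.20) and ATRNL1 (8.11, SE 0.37). TIMP4 and CD200R1 had 1 control read each, which gives ratios of 4974 (counting interval 892 to 196490) and 1834 (329 to 72452). All 6 control reads of HABP2 lay in 1 library, and its value ranged from 8.04 to 12.76 when 1 library was left out. Among the largest falls were those of the fibrillar collagen COL3A1 (-6.70, SE 0.80; 3474 to 33.3 CPM), HMCN2 (-6.02, SE 0.42), the peptide receptor VIPR1 (-4.91, SE 0.80), CREB3L1 (-4.68, SE 0.42), AIF1L (-4.06, SE 0.39), PRND (-4.00, SE 1.08), SELE (-3.79, SE 0.37), BIRC3 (-3.76, SE 0.28) and MAP1A (-3.57, SE 0.55).

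Of 15881 genes tested, 2047 were higher and 1941 lower in the libraries labelled MAF KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 746 and 827 of them by at least 2-fold. The groups did not overlap for 6983 genes (44.0%), where chance gives 10%. With upper-quartile scaling the counts were 1668 and 2548, so 39.6% of called genes were higher, and the log2 fold changes shifted by a median of -0.08. Without control replicate 2 they were 1334 and 1233, and without control replicate 3 they were 1360 and 1279. The PRND call was lost without control replicate 1 (adjusted p = 0.0821), control replicate 2 (0.116), or replicate 2 (0.129) or 3 (0.0844) of the libraries labelled MAF KO, in edgeR.

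Of 30 members of the LSEC list, genes of liver sinusoidal endothelium, 18 were expressed enough to be tested, and 12 rose and 0 fell, with 14 rising when adjusted over the list alone. Beside MRC1, CRHBP and STAB2, the rises were those of the co-receptor CD14 (log2 fold change 6.94, SE 0.58), CCL14 (5.69, SE 0.34), the nuclease DNASE1L3 (5.22, SE 0.46), the fatty acid receptor CD36 (5.11, SE 0.26), CLEC4M (3.75, SE 0.94), CTSL (1.68, SE 0.13), STAB1 (1.66, SE 0.18) and FLT4 (1.56, SE 0.17). CLEC4G had 0 control reads against 42, which makes it at least 12.4-fold higher. The values of members without a call were 3.03 for LYVE1 (SE 0.98), 1.15 for TFEC (SE 0.60), 0.96 for F8 (SE 0.31), -0.01 for IL1R1 (SE 0.45), -0.07 for BMP2 (SE 0.25) and -0.24 for LIFR (SE 0.18). Members too low to test stayed low in most libraries. GATA4 had 0 reads in each, and FCN3 had 4, 2 and 1 control reads against 7, 1 and 21. OIT3 had 11, 15 and 6 against 5, 6 and 1, and CCL23 had 2, 10 and 4 against 194, 29 and 9. CLEC1B, FCN2, FCGR2B, CD209, CD4, WNT2, RAMP3 and HAMP had at most 22 reads in any library.

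The median log2 fold change of the LSEC list was 3.39, or 3.33 with CLEC4G at its bound (camera adjusted p = 1.49e-08 over 30 lists; adjusted p = 0.616 with an estimated correlation). That median covers members that passed the expression filter, some of them only through the libraries labelled MAF KO, and without the filter it was 1.69. All 8 list calls that camera made with its preset correlation of 0.01 were lost with an estimated correlation between genes. The test fry made 14 list calls, 5 of them among these 8, and had none for interferon (fry adjusted p = 0.123), hypoxia and glycolysis (0.0579) and amino acid and ER stress (0.111). Fry tests a list on its own, while camera sets it against all other genes. Fry alone called the endocytic (fry adjusted p = 0.00199), flow (0.00312) and blood cell (0.0122) lists upward. It did so too for the lymphatic (0.018), pan-endothelial (0.0246) and MAF family (0.0388) lists. In the endocytic list 4 members rose and 4 fell, with a median log2 fold change of -0.0193. In the pan-endothelial list 6 rose and 6 fell, with a median of 0.0889, so these 2 calls show no general rise. Falls called by fry alone were those of the p53 (fry adjusted p = 0.00991), mesenchymal (0.0246) and NF-kB (0.0373) lists. The CLEC4M call was lost without any of the libraries except replicate 3 labelled MAF KO, with edgeR adjusted p from 0.0673 to 0.119. LYVE1 passed without control replicate 2 (edgeR adjusted p = 0.0425) or replicate 3 labelled MAF KO (0.0449), and F8 passed without replicate 1 labelled MAF KO (0.0299).

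**Figure D3:**
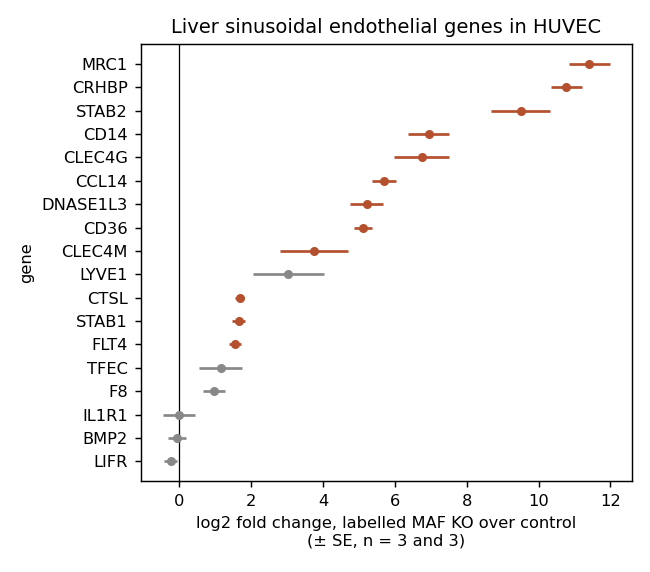
Log2 fold change (horizontal axis, ± SE, 3 libraries per group) of each tested LSEC list gene in HUVEC. Red points are the 12 genes that rose, grey points those without a call, from MRC1 at 11.41 to LIFR at -0.24. CLEC4G, with 0 control reads, is shown at its fitted value, which is not a bound.

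Cell cycle genes fell more often than they rose. All 30 mitosis genes fell, with a median log2 fold change of -2.46, among them the centromere histone CENPA (-2.96), the motor KIF11 (-2.32) and PRC1 (-2.34) (camera adjusted p = 4.37e-17; adjusted p = 0.616 with an estimated correlation). Of 34 DNA replication genes 21 fell and 1 rose, with falls of CLSPN (-2.64), the nuclease EXO1 (-1.92) and FEN1 (-0.98) (camera adjusted p = 2.51e-08; adjusted p = 0.616 with an estimated correlation). Of 21 p53 targets 7 fell and 2 rose, and BTG2 (-1.52), PLK3 (-0.83) and TIGAR (-0.55) fell (camera adjusted p = 0.0696).

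Lysosomal genes rose more often than they fell. Of 37 tested, 19 rose and 1 fell, led by the protease LGMN (5.34, SE 0.11), CTSL and the cholesterol carrier NPC2 (1.52) (camera adjusted p = 6.23e-06; adjusted p = 0.616 with an estimated correlation). Of 29 hypoxia and glycolysis genes 9 rose and 0 fell, among them the glucose transporter SLC2A3 (3.20), GPI (1.11) and KDM3A (0.88) (camera adjusted p = 0.00282; adjusted p = 0.689 with an estimated correlation). Without replicate 3 labelled MAF KO that call was lost (camera adjusted p = 0.0871). Of 22 endocytic receptor genes 4 rose and 4 fell, with DAB2 (2.71) and the clathrin light chain CLTA (0.79) higher and CUBN (-2.17) lower (camera adjusted p = 0.911, fry adjusted p = 0.00199).

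Of 34 interferon-responsive genes 7 rose, 0 fell and 27 had no call, among them IFIT2 (2.08, SE 0.18), OAS1 (3.65, SE 0.83) and HERC5 (2.08, SE 0.45), with a list median of 2.08 (camera adjusted p = 1.21e-05; adjusted p = 0.689 with an estimated correlation). The median CPM of the list ranged from 10.3 to 17.8 in controls and was 21.1, 30.9 and 112 in the libraries labelled MAF KO. Without replicate 3 of both groups the list median was 1.01 and 14 members rose (camera adjusted p = 2.68e-08; adjusted p = 0.638 with an estimated correlation). The OAS1 call was lost without control replicate 1 (edgeR adjusted p = 0.0827), control replicate 2 (0.0923) or replicate 2 labelled MAF KO (0.0518). When 1 library was left out, OAS1 ranged from 2.61 to 4.28. HERC5 was lost without control replicate 1 (0.0748), 2 (0.0829) or 3 (0.0509), or replicate 2 labelled MAF KO (0.0538), in edgeR. Of 18 antigen presentation genes 3 rose and 1 fell, with PSMB10 (1.12) and TAPBP (0.62) higher and CD74 (-2.68) lower (camera adjusted p = 0.37).

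Secreted endothelial factors fell more often than they rose. Of 24 angiocrine factors 9 fell and 3 rose, with falls of the growth factors KITLG (-2.38), BMP4 (-2.10) and PDGFB (-1.23) (camera adjusted p = 0.0324; adjusted p = 0.616 with an estimated correlation). That call was lost without control replicate 2 (camera adjusted p = 0.0621) or replicate 3 labelled MAF KO (0.0622), and with upper-quartile scaling (0.0900). Of 26 inflammatory NF-kB genes 9 fell and 4 rose, and the chemokine CCL2 (-2.83), RELB (-1.32) and BIRC3 fell (camera adjusted p = 0.152). Of 17 BMP and TGF-beta targets 6 fell and 2 rose, with LTBP2 (-1.13) and NOG (-3.06) lower and SMAD9 (1.64) higher (camera adjusted p = 0.37). Of 27 mesenchymal genes 13 fell and 7 rose, with CCN1 (-1.50) and TAGLN (-1.50) lower and the transcription factor SNAI2 (3.90) higher (camera adjusted p = 0.0909).

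General and subtype-specific endothelial genes went both ways. In the list of continuous endothelium and basement membrane 6 of 20 rose and 6 fell, with NID1 (2.99) and COL4A1 (1.31) higher and HSPG2 (-2.16) lower (camera adjusted p = 0.874). Of 24 pan-endothelial genes 6 rose and 6 fell, with the angiopoietin receptor TEK (1.91) and ETS1 (0.46) higher and ECSCR (-0.61) lower (camera adjusted p = 0.577). Of 19 arterial genes 4 rose and 5 fell, with DLL4 (0.74) higher and BMX (-2.27) and CLU (-2.88) lower (camera adjusted p = 0.377). Of 8 venous genes 4 rose and 2 fell, with NRP2 (2.18) and VCAM1 (3.68) higher and SELE lower (camera adjusted p = 0.483). Of 11 lymphatic genes 3 rose and 2 fell, with FLT4 higher and ANGPT2 (-2.26) and EFEMP1 (-1.05) lower (camera adjusted p = 0.326). Of 19 tip cell genes 6 rose and 6 fell, with TEK and FLT1 (1.29) higher and PDGFB lower (camera adjusted p = 0.652). Of 11 Notch targets 4 rose and 1 fell, and DLL4, EFNB2 (2.01) and HES4 (1.09) rose (camera adjusted p = 0.135). Of 14 flow-responsive genes 6 rose and 3 fell, and HMOX1, a haem-degrading enzyme (3.82), the iron exporter SLC40A1 (2.68) and CYP1B1 (7.01, SE 0.81, with 6 control reads; 6.44 to 8.71 when 1 library was left out) rose (camera adjusted p = 0.0601).

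Of 30 genes of the amino acid and ER stress response 2 rose and 3 fell, with SLC3A2 (1.38) and HERPUD1 (0.38) higher and ATF5 (-0.59) lower (camera adjusted p = 0.0351; adjusted p = 0.689 with an estimated correlation). That call was lost without control replicate 2 (camera adjusted p = 0.0676) and without replicate 1 (0.0690) or 2 (0.132) labelled MAF KO. Of 28 cholesterol and fatty acid genes 4 fell and 1 rose, namely FADS1 (-0.66), TM7SF2 (-0.51) and DHCR7 (-0.35) among the falls (camera adjusted p = 0.43). Of 24 NRF2 and antioxidant genes 4 rose and 4 fell, with HMOX1 higher and MT1E (-2.14) and ME1 (-0.92) lower (camera adjusted p = 0.652). Of 10 genes of the MAF family other than MAF 3 rose, namely MAFG (0.39), BACH2 (0.73) and BACH1 (0.44) (camera adjusted p = 0.355). Of 23 mitochondrial genes CYCS (-0.64) and ATP5MC1 (-0.36) fell (camera adjusted p = 0.377), and of 28 ribosomal protein genes RPSA (-0.60) fell (camera adjusted p = 0.135; 0.00955 without replicate 2 labelled MAF KO).

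Markers of other cell types were mostly too low to test. Of 23 blood cell and macrophage markers 3 were tested, and AIF1 (5.91) and RUNX1 (1.02) rose (camera adjusted p = 0.247). Of 11 fibroblast and smooth muscle markers 4 were tested, and PDGFRA (2.77) rose and RGS5 (-2.09) fell (camera adjusted p = 0.911). Of 15 epithelial and hepatocyte markers 5 were tested, and the keratins KRT18 (-1.59), KRT7 (-2.97) and KRT8 (-0.68) fell (camera adjusted p = 0.0601). When 1 library was left out, KRT7 ranged from -3.68 to -1.95. The calls of KRT7, KRT8, BACH1, BACH2, DHCR7 and TM7SF2 were each lost without at least 3 single libraries, with edgeR adjusted p from 0.0513 for TM7SF2 to 0.141 for KRT8.

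**Figure D4:**
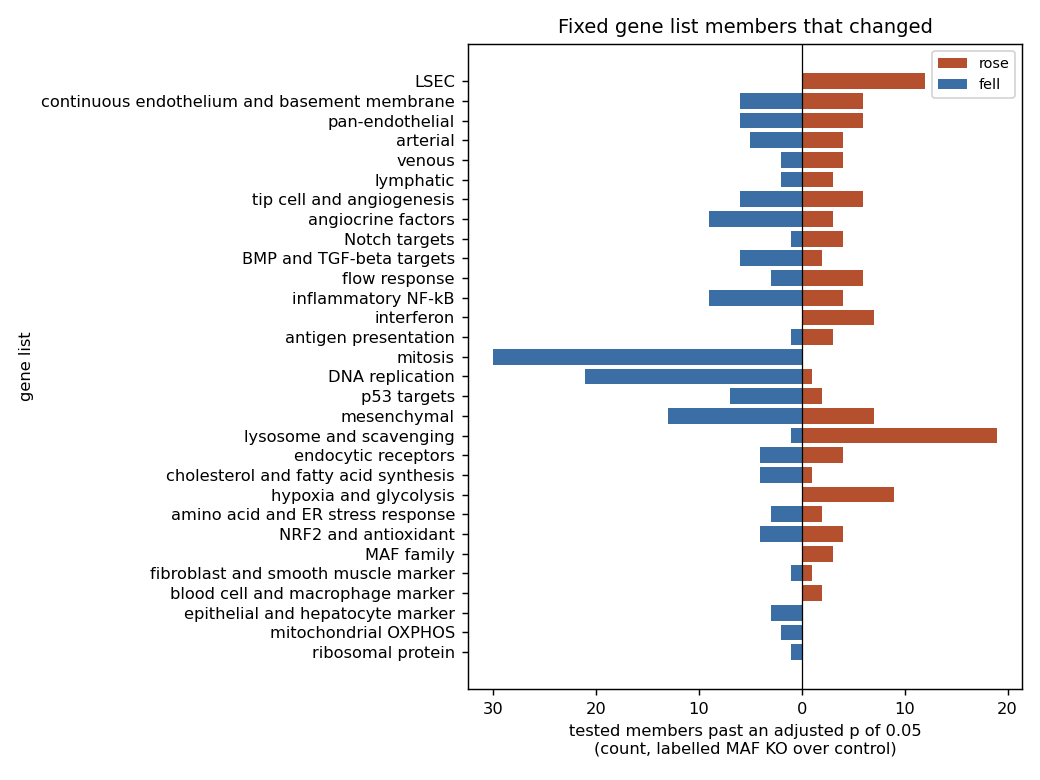
Number of tested members (horizontal axis) of each of the 30 gene lists that rose (red, to the right) or fell (blue, to the left) in the libraries labelled MAF KO. All 30 mitosis genes fell, and 12 LSEC list genes rose with 0 falling.

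Genes that marked sinusoidal cells in the liver sample rose more often than they fell in HUVEC, and those that marked its vascular cells fell more often than they rose. Of the 100 genes highest in the LSEC-like class relative to the vascular and venous classes, 87 were tested, 50 rose and 6 fell, with a median log2 fold change of 0.90. That median depended on list size, at 1.7 with 50 genes and 0.575 with 200. Among the leading liver genes, MS4A6A (5.61), FRZB (3.35) and RELN (1.92) rose beside SLC7A8 and CLEC4M. PVALB rose from 2 to 1027 reads, a ratio of 455 (126 to 3764), and SH3TC1 (0.25) had no call. Of the 100 genes highest in the vascular and venous classes, 93 were tested, 27 fell and 13 rose, with a median of -0.25. The median was -0.767 with 50 genes and -0.123 with 200. CD34 (-2.53), IL6 (-2.19), SELP (-2.15), CCN2 (-1.58) and VIM (-0.77) fell, AQP1 (1.46) rose, and FBLN2 (0.74), VWF (-0.48), CPE (-0.85) and SYNPO (0.20) had no call. When adjusted over the list alone, 57 rose and 7 fell of the sinusoidal list, and 33 fell and 15 rose of the vascular list. Camera gave an adjusted p of 7.16e-15 for the sinusoidal and 0.00355 for the vascular list over both lists, and with an estimated correlation 0.00484 and 0.0299. The LSEC list was adjusted over 30 lists, a stricter correction, so its adjusted p cannot be set beside these. Before adjustment, camera with an estimated correlation gave p = 0.00242 for the sinusoidal, 0.0299 for the vascular and 0.0414 for the LSEC list. Adjustment over all lists together was not made. The vascular call at an estimated correlation was lost with 50 genes (camera adjusted p = 0.182), with 200 genes (0.0632) and with venous cells alone (0.117). Of the sinusoidal list, 14 genes are also in the LSEC list, and without them the camera adjusted p was 2.20e-12.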

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

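The tests of a wrong label, of exchanged labels, of a replicate 3 batch and of the splits of libraries were chosen only after the results were seen; those of the region around MAF and of the immunoglobulin counts were written beforehand, but that any part of a gene counts as within the region was settled after a first result.

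The RNA in liver barcodes with fewer than 50 genes was outside every comparison, and 9 genes inspected there stood above the 2.13 UMIs per 1000000 (CPM) that a count of 0 allows. Over 188619 such barcodes with 1410907 UMIs, the levels were 27104 CPM for IGLL5, 12724 for JCHAIN, 13243 for B2M, 5181 for FCN3, 2080 for CLEC4G, 1102 for STAB2, 703 for ALB, 526 for MAF and 90.0 for VWF. No biological explanation was tested for these.

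The first pattern is the 11.95 log2 rise of MAF RNA in libraries labelled MAF KO. A single wrong label is excluded, since 3 of 3 libraries labelled MAF KO stood above every control. On MAF RNA alone, exchanged labels of both groups cannot be told apart from MAF RNA made from an added copy. Both predict that 6 of 6 libraries are out of place, as they were, and no library of known identity decides. The titles place the term MAF only in the libraries with high MAF RNA. The titles thus go with the RNA, and only the knockout label goes against it. A rise of the whole region around MAF was not seen. Only 2 genes with any part within 1 Mb of MAF were tested, fewer than the 3 asked for. WWOX had no call (log2 fold change -0.37, edgeR adjusted p = 0.134) and CDYL2 fell (-0.60, edgeR adjusted p = 0.0217). The 30 other genes of that window together held 10569 reads in the controls and 7867 in the libraries labelled MAF KO. Most of them had few or no reads in either group, so the question stays open for the window as a whole. A knockout that only leaves MAF transcripts in place predicts no more MAF RNA than in the controls. The rise from 0.317 to 1244 CPM argues against it as the whole explanation. A knockout that also raises MAF RNA was not tested.

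The second pattern is the higher median of the interferon list, of which 7 of 34 genes had a call. Replicate 3 was the highest control for 91.2% of the 34 interferon genes and the highest library labelled MAF KO for all 34, so a batch or origin shared by the replicate 3 libraries is a candidate explanation of part of the rise. It is excluded as the whole source, since without replicate 3 of both groups the list median was 1.01 (camera adjusted p = 2.68e-08; adjusted p = 0.638 with an estimated correlation). A difference that goes with the label stays open.

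The last pattern is immunoglobulin RNA in the venous-like liver cells, where IGLL5 stood at 49221 CPM against 454 in vascular cells. Free RNA as its main source is excluded for IGLL5, because 90.3% of its 7656 UMIs lay in 1 cell and 94.0% in 3 cells. A few droplets joined with plasma cells, or plasma cells placed in this class, may account for it, and these were not told apart. JCHAIN was less concentrated, with 42.9% in 1 cell and 67.3% in 3, and no biological explanation was tested.

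The 6 HUVEC libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3988 genes, an LSEC list median of 3.39 and a sinusoidal list median of 0.898, each reached by 1 of the 10 splits; the highest other split gave 0 genes, 1.29 and 0.322.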

How the results depend on the processing

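The alternatives without replicate 3 of both groups, with replicate 3 as a batch term, with venous cells alone and with the earlier naming rules were chosen only after results were seen; the others were planned. The numbers of higher and lower genes were 2060 and 1928 with median-of-ratios factors, 1946 and 1757 without a filter, 2122 and 1992 with a stricter one, 2384 and 2203 by DESeq2, 1507 and 1396 without replicate 3 of both groups (2536 of 2903 calls shared) and 2391 and 2329 with replicate 3 as a batch term. They moved to 1020 and 830 at an adjusted p under 0.01, to 746 and 827 at 2-fold or more, and ranged from 1334 to 2001 and from 1233 to 1870 when 1 library was left out. Fewer libraries or a stricter threshold give fewer calls by construction. MAF kept its rise, from 11.35 to 12.30. On the pairing, deviations of same-numbered libraries correlated with r = -0.107, -0.142 and 0.605 for numbers 1, 2 and 3. The libraries numbered 3 thus deviated together, while those numbered 1 and those numbered 2 did not. Not every library correlated best with its own number: r was 0.539 for control 1 with replicate 2 labelled MAF KO and 0.532 for control 2 with replicate 1, a hint from the data and not the design; a replicate block gave 1803 and 1712 genes.

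The LSEC list kept its direction and call except with an estimated correlation (camera adjusted p = 0.616); the lowest p over its 15 alternatives was 3.18e-10, and its median fell to 1.69 without a filter, which adds low genes. The sinusoidal list kept its call in 21 alternatives (camera p from 2.45e-19 to 0.00242, not adjusted over lists). The vascular list did so with an unadjusted p up to 0.0299, but list size and estimated correlation together ended its call. With symbols as deposited and the earlier naming rule, camera with an estimated correlation gave the vascular list p = 0.115. Of the other lists, 17 of 435 comparisons lost and 25 gained a call. When 1 library was left out, calls were gained by the ribosomal (lowest camera adjusted p = 0.00955), epithelial (0.0257), mesenchymal (0.0287), flow (0.0407) and p53 (0.0418) lists. Of 114 other named genes 92 kept direction and side throughout and 22 did not; of 1596 comparisons 1512 were unchanged, 57 lost and 19 gained a call. IL1R1, without a call in any, changed sign to 0.0039 without a filter, to 0.35 without replicate 3 of both groups, 0.15 without control replicate 2, 0.37 without replicate 3 labelled MAF KO and 6.24e-04 by DESeq2. BMP2, also without a call, went to 0.0896 without replicate 3 of both groups, 0.15 without control replicate 2 and 0.12 without replicate 3 labelled MAF KO. With 1 library left out BMP2 ranged from -0.24 to 0.15 and IL1R1 from -0.36 to 0.37; the cause was not tested.

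Liver shares depended on clustering. At resolution 0.5 they were 52.0% LSEC-like, 0% vascular, 0% venous and 22.7% unnamed, with MAF at 792 in the LSEC-like class. At resolution 2.0 they were 27.6% LSEC-like, 20.1% vascular, 20.7% plasma-cell-like and 26.0% unnamed, with MAF at 9.59 in the last but one. With at least 500 genes per cell they were 26.6% vascular, 7.69% venous and 12.6% unnamed, with MAF at 8.93 in plasma-cell-like cells. With doublets kept they were 34.6% LSEC-like and 17.5% unnamed, with MAF at 967 in LSEC-like cells. The earlier naming rule left 0% plasma-cell-like and 55.0% unnamed, and with symbols as deposited 17.8% LSEC-like, 14.2% plasma-cell-like (MAF 5.03) and 46.2% unnamed. As a mean of each cell's own level MAF was 1199 in LSEC-like, 353 in vascular and 70.0 in plasma-cell-like cells, and after thinning its shares were 47.5%, 19.8% and 2.67%. Genes at least 2-fold higher in sinusoidal and in vascular cells ranged from 263 to 468 and from 305 to 461. In every alternative that named both classes, MAF was higher in LSEC-like than in vascular cells; the cause of the moves was not tested.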

Other observations

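The comparison of liver and HUVEC genes was chosen only after the list results were seen. A shift along the sinusoidal against vascular axis was tested across 5811 genes with at least 30 UMIs in the liver classes. Spearman's rho between that liver ratio and the HUVEC fold change was 0.188. It was 0.00615 for the liver ratio of the venous-like over the vascular-endothelium-like class. Genes are not independent replicates, so no p is given. As a hypothesis only, the small rho of 0.188 leaves room for a weak general shift toward sinusoidal expression in the libraries labelled MAF KO. Whether leading genes carry such a shift more than all genes was not tested.

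FN1, which encodes fibronectin, took 1.19%, 0.883% and 1.23% of reads in the controls and 2.27%, 4.07% and 4.65% in the libraries labelled MAF KO. FOLR2, a folate receptor, had 1 read in the controls and 527 in the libraries labelled MAF KO, a ratio of 467 (83.5 to 18489), and the gelatinase MMP9 had 2 and 114 reads, a ratio of 50.5 (13.7 to 422). These 3 genes were chosen after their values were seen. The share of mitochondrial reads ranged from 3.28% to 3.90% in the controls and from 2.02% to 5.10% in the libraries labelled MAF KO. The first principal component held 64.3% of variance and separated the groups, and the second held 17.9% and set replicate 3 of both groups apart.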
